A study of Homo sapiens with 6 samples.

How the data were processed

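RNA of human monocytes and macrophages, unstimulated or stimulated with flagellin of Salmonella Typhimurium, was measured on 6 Affymetrix arrays. Per the labels' protocols, total RNA was copied into cDNA with an oligo(dT) primer, transcribed into biotin-labelled cRNA and hybridised after a check of each cRNA on a test array. The labels name an older human array, whereas the deposited table holds 54675 probe sets, more than that array carries, with names that match the platform annotation supplied with the series. The labels give no dose, stimulation time, tissue, donor or way of obtaining the macrophages. The deposited values are linear probe set intensity values, 1 colour, and how the authors summarised, background-corrected or scaled them is not given in the sources used here. The deposited intensity values were all above 0, and the array medians of log2 intensity differed by 0.67.

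Each array was placed in 1 of 4 groups from its title. The groups were unstimulated macrophages (n = 2), unstimulated monocytes (n = 2), flagellin-stimulated macrophages (n = 1) and flagellin-stimulated monocytes (n = 1). No label says whether replicate arrays came from separate donors or cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. The labels give the replicate numbers 1 and 2 in both unstimulated groups without saying that a number marks a shared donor or day, so no pairing was used.

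The rules for values, tests, named genes and 29 gene lists were fixed before the data were examined. Because the array medians differed by over 0.3 on the log2 scale, the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Normalized intensity was floored at its 20th percentile, 14.2, and log2 transformed. The 62 control probe sets were left out of the tests. Of the probe sets, 41091 carried exactly 1 gene symbol, 1801 carried several and 11721 other probe sets carried none. Symbols were updated through gene identifiers for 41037 probe sets. No gene was named from a probe set with several symbols. XIST, TSIX and genes of the Y chromosome (95 probe sets) were left out. A gene was represented by its probe set of highest mean, and 14782 of 19740 genes were tested because that mean reached the 40th percentile of all probe sets, 4.67 on the log2 scale. Cross-hybridisation between close family members, such as the metallothioneins, could not be separated.

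One model with a mean for each of the 4 groups was fitted with limma (lmFit, then eBayes with a mean-variance trend). It has 2 residual degrees of freedom, all from the unstimulated pairs, and 4.59 prior degrees of freedom. The lone flagellin array of each cell type is assumed to vary like the unstimulated arrays. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Stimulated macrophages and monocytes, 1 array each, were compared by values without a test. Values at the floor have no order, so a fold against a group with all arrays at the floor is a limit on the normalized scale only. Changes are log2 differences, and SE is the moderated standard error from limma.

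Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. With the preset correlation camera sets the genes of a list against the other genes. Its small p-values therefore do not measure the spread between arrays or stand for replication. For the 1 against 1 comparison, each list median was set against 10000 random lists of the same size matched on mean expression. A further 11 lists, for epithelial, hepatocyte, plasma, stromal, endothelial, mast, pan-leukocyte and housekeeping genes, were written after a first look at the values. Named genes were TLR5 and, for the unstimulated comparison, the 12 highest and 12 lowest changes among called genes whose arrays did not overlap between groups. For flagellin in both cell types together the rule took up to 10 genes each way that moved the same way in both. For each single flagellin contrast it took 5 each way. These flagellin lists were filled by size among genes at an unadjusted p under 0.05 where too few were called. For the stimulated arrays it took the 10 largest differences each way. For each gene list described, up to 4 members with the largest change were named. TLR4, NAIP, IL27, IFI27, CCL20, C1QA, C1QB, CLEC10A, CMTM2, RRM2, SOAT1, IL10, IL7R and the members named from the 11 later lists fall outside this rule and were chosen after their values were seen.

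The fit was tested on simulated arrays with the observed means and spreads over 14782 genes and 200 changed genes. For the unstimulated comparison it recovered 2.9% of 2-fold, 20.6% of 4-fold, 66.7% of 8-fold, 90.9% of 16-fold and 100% of 64-fold changes, with 8 false calls. For flagellin in monocytes it recovered 0% of 2-fold, 14.7% of 4-fold, 42.4% of 8-fold, 60.6% of 16-fold and 93.9% of 64-fold changes, with 9 false calls. Simulated genes varied independently, without a floor or a cell type difference, so these shares need not hold on the real arrays. IL6 changed 76.6-fold with flagellin in monocytes and was not called (limma adjusted p = 0.386). Camera with the preset correlation gave p = 3.44e-08 for a simulated list of 20 genes shifted by 1 log2 on the flagellin monocyte array, and p = 0.0399 with an estimated correlation. Of 200 simulated lists without a shift, 9 had a camera p under 0.05 with the preset correlation and 0 with an estimated one.

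Alternatives were the values as deposited, arrays centred on their medians, other floors, a pseudocount of 16, no filter or a 60th percentile filter, no trend, the mean of a gene's probe sets, all probe sets, each unstimulated array left out in turn, a replicate block, and fits to the unstimulated arrays alone or with additive terms. Fits to the 3 arrays of 1 cell type alone, and the flagellin monocyte array against each unstimulated monocyte array, were added after seeing the data. The number of arrays limits the precision of every value.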

Results

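Gene expression was measured in human monocytes and macrophages with and without flagellin, the bacterial filament protein that is recognised at the cell surface by the receptor TLR5. There were 2 arrays of unstimulated macrophages, 2 of unstimulated monocytes, and 1 of each cell type after flagellin. Median deposited intensity was 30.5, 33.3 and 32.4 on the macrophage arrays and 20.9, 25.1 and 25.6 on the monocyte arrays. The 99th percentile of intensity was lower on the macrophage arrays, at 544, 276 and 508 against 971, 2101 and 2888, while the highest intensity was above that of the monocyte arrays, at 22424 to 22995 against 17384 to 18555. Across probe sets, which are not independent replicates, log2 intensities of 2 macrophage arrays correlated at r = 0.80 to 0.91. Pairs of monocyte arrays correlated at 0.83 to 0.96, and a macrophage with a monocyte array at 0.33 to 0.59.

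TLR5 was measured by 1 probe set and was close to the floor on 5 of the 6 arrays. Deposited intensity was 132 on unstimulated monocyte array 1 and 18.3 to 23.4 on the other arrays. The unstimulated macrophage minus monocyte change was -1.72 (SE 0.69, n = 2 against 2, limma adjusted p = 0.12). It was -0.60 without unstimulated monocyte array 1 and -2.84 without array 2. The adjusted p was 0.0366 with the replicate number as a block, a pairing the labels do not state, and 0.104 to 0.391 in the other alternatives. Among the tested parts of the intracellular flagellin sensor, NLRC4 was lower on the macrophage arrays by -4.04 (SE 0.39, adjusted p = 0.0155). The change of NAIP, which binds flagellin in that pathway, was 2.02 (SE 0.75, adjusted p = 0.11) and did not pass.

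The first comparison asked how unstimulated macrophages differed from unstimulated monocytes. The genes most strongly higher on the macrophage arrays were RBP2, FABP1, APOA4, PCK1, APOC3, ADIRF, TMC5, SI, CYP3A5, PHGR1, APOA1 and PIGR, with log2 changes of 8.08 to 8.92 (n = 2 against 2, limma adjusted p = 0.0155 for each). Several of these are known for the absorption and transport of fat and vitamin A in the small intestine: FABP1 binds fatty acids, RBP2 binds retinol, and APOA4, APOC3 and APOA1 are apolipoproteins. SI encodes the brush border enzyme sucrase-isomaltase, and PIGR carries immunoglobulin A across epithelia. APOA4 averaged 12.8 ± 0.16 (SD, n = 2) in macrophages and 4.07 ± 0.18 (SD, n = 2) in monocytes on the log2 scale, a change of 8.75 as normalized, 7.63 as deposited and 7.27 after centring arrays on their medians. On the unstimulated monocyte arrays APOA4 read 11.94 and 16.83 as deposited, under the array medians of 20.9 and 25.1. RBP2, PCK1, APOC3, TMC5, PHGR1 and PIGR also read under these medians, so the changes of these genes are only limits. FABP1, SI, ADIRF and CYP3A5 were at the floor on all monocyte arrays after normalization. Their changes against the floor were 8.76, 8.14, 8.21 and 8.12 as normalized and 7.34, 6.42, 6.54 and 6.39 as deposited, so the fold depended on the scaling.

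The genes most strongly lower on the macrophage arrays were S100A8, VCAN, TYROBP, LGALS1, HCLS1, CD44, CD14, VIM, AIF1, FCN1, LSP1 and BCL2A1, with log2 changes of -8.50 to -6.58 (limma adjusted p = 0.0155, and 0.0202 for VCAN). S100A8 is a calcium-binding protein abundant in monocytes and neutrophils, CD14 is the lipopolysaccharide co-receptor, and TYROBP is a signalling adaptor of myeloid receptors. S100A8 averaged 4.39 ± 0.79 (SD, n = 2) in macrophages and 12.9 ± 1.47 in monocytes, a 363-fold difference. CD14 averaged 4.13 ± 0.42 and 10.9 ± 0.12, a 111-fold difference. On the unstimulated macrophage arrays deposited intensity was 15.2 and 36.8 for S100A8 and 14.98 and 25.5 for CD14. These values were close to or under the array medians of 30.5 and 33.3, so both folds are only limits. LSP1 and BCL2A1 were at the floor on both unstimulated macrophage arrays, with changes against the floor of -6.65 for LSP1 and -6.58 for BCL2A1 as normalized and -7.05 and -6.84 as deposited.

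**Figure D1:**
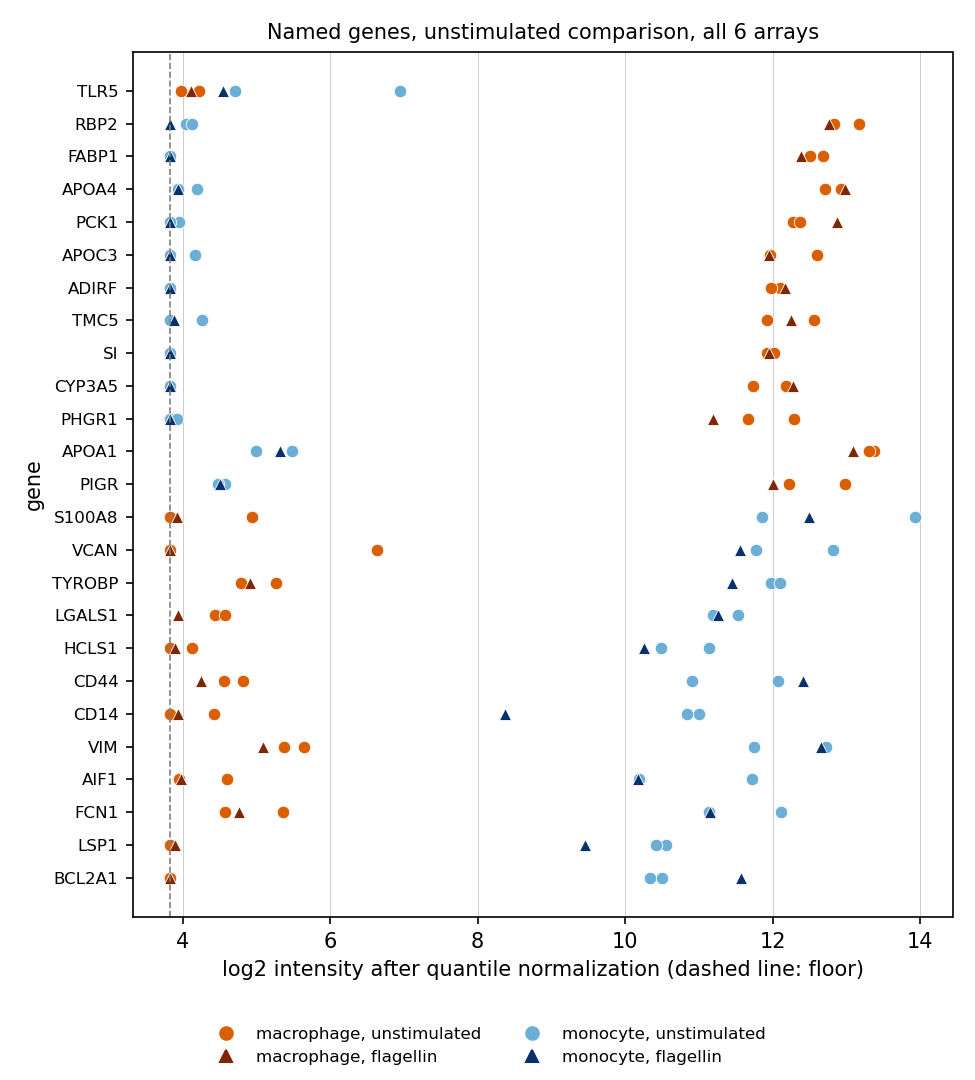
Log2 intensity after quantile normalization (x axis) of TLR5 and the 24 named genes of the unstimulated comparison (y axis), with 1 point per array, circles for unstimulated and triangles for flagellin arrays. The macrophage and monocyte points of each gene lie apart, those of TLR5 by less than those of the other genes, also on the flagellin arrays. The flagellin arrays did not enter the change that ranked these genes. They did enter the normalization, the choice of probe sets and the filter.

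In all, 2032 of 14782 genes were called, 677 higher and 1355 lower on the macrophage arrays, so 33.3% were higher. This split depended on the scaling: 2128 were higher and 2074 lower in the values as deposited, and 644 higher and 2478 lower after centring arrays on their medians. The median change of all tested genes was 0.34 as normalized, 0.44 as deposited and -0.05 after centring, and the changes are to be read against it. With any 1 of the 4 unstimulated arrays left out, or with all 19740 genes tested, no gene was called. The lowest limma adjusted p was then 0.0503 to 0.148 with an array left out and 0.0678 without the filter, while all 2032 genes kept their direction. At an unadjusted p under 0.05, 2430 to 6558 genes passed with an array left out and 5779 without the filter.

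Genes that mark monocytes were lower on the macrophage arrays: 16 of 20 measured members were called lower and 0 higher (18 lower adjusted over the list alone), with a median of -5.26. Examples are CD14, FCN1, S100A8 and VCAN. The camera adjusted p was 1.8e-12 with the preset correlation, and adjusted p = 0.36 with an estimated correlation, while the fry adjusted p was 0.0198. Of 23 genes known to rise in macrophage differentiation, 0 were called higher and 4 lower, both over all genes and adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.26). The scavenger receptors CD163 (-4.12, adjusted p = 0.0191) and MARCO (-3.22, adjusted p = 0.0209) were among the lower ones, as were the complement genes C1QA (-2.15, adjusted p = 0.0222) and C1QB (-1.60, adjusted p = 0.0328). The change was -2.72 for SPP1 (adjusted p = 0.19) and -2.35 for GPNMB (adjusted p = 0.16), so neither passed.

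Among receptor and sensing genes of innate immunity, 4 lists passed camera with the preset correlation and none with an estimated one. Each passed fry. The fry adjusted p was 0.012 for the Toll-like receptor, 0.0198 for the Fc, scavenger and complement receptor, 0.0216 for the inflammasome and 0.0198 for the class II list. In the Toll-like receptor list 9 of 23 members were lower and 0 higher (11 lower adjusted over the list alone), among them CD14, TLR2 (-4.63), TLR8 (-4.36) and TLR4 (-3.52), with camera adjusted p = 0.000234. Fc, scavenger and complement receptors held 9 of 17 lower members and 0 higher (11 lower adjusted over the list alone), among them FCER1G (-6.33), C5AR1 (-6.11), ITGAM (-5.07) and ITGAX (-4.99), with camera adjusted p = 2.1e-05. The inflammasome list, with 6 of 17 lower and 1 higher (the same counts adjusted over the list alone), included NLRP3 (-4.33) and the protease CASP1 (-4.07), with camera adjusted p = 0.029. Major histocompatibility class II and co-stimulation genes held 5 of 15 lower and 0 higher (6 lower and 1 higher adjusted over the list alone), including HLA-DPA1 (-4.60) and HLA-DPB1 (-4.29), with camera adjusted p = 0.0126. Each of these lists had adjusted p = 0.36 in camera with an estimated correlation. Their estimated correlations were below 0, at -0.0504 to -0.00208, so this loss is not a measure of gene correlation alone.

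Among inflammatory mediators, 5 of 19 cytokine genes were lower and 1 higher (the same adjusted over the list alone), led by IL1B (-6.58) and PTGS2 (-5.81), while IL27 was higher (2.21). Camera gave an adjusted p = 0.0144, and adjusted p = 0.42 with an estimated correlation. Of 16 chemokines, 4 were lower and 0 higher (the same adjusted over the list alone), namely CXCL3 (-5.85), CCL4 (-5.60), CXCL2 and CCL20 (-4.65), with camera adjusted p = 0.00271. NF-kB feedback genes, which respond to and restrain that transcription factor, had 4 of 21 lower and 0 higher (12 lower adjusted over the list alone), such as SOCS3 (-4.31) and SOD2 (-3.99), with camera adjusted p = 2.1e-05. Interferon-stimulated genes had 5 of 24 lower and 1 higher (7 lower and 1 higher adjusted over the list alone), with MX2 at -3.37 and IFI27 at 2.03, and camera adjusted p = 0.00321. The last 3 lists had adjusted p = 0.36 with an estimated correlation. By fry the cytokine and NF-kB feedback lists passed (adjusted p = 0.0342 and 0.0467). The chemokine and interferon-stimulated lists did not (fry adjusted p = 0.105 and 0.0952).

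Genes of the lysosome were also lower, with 7 of 23 called and 0 higher (the same adjusted over the list alone), including CTSS (-6.04), PSAP (-5.33) and LAMP2 (-5.03). Camera gave an adjusted p = 4.7e-05, and adjusted p = 0.36 with an estimated correlation, and fry an adjusted p = 0.0321. In glycolysis 4 of 19 were lower and 0 higher (7 lower adjusted over the list alone), with HK1 at -5.26 and HK3 at -4.80. Matrix remodelling genes had 4 of 15 lower and 0 higher (6 lower adjusted over the list alone), with TIMP1 at -5.78 and PLAUR at -4.64. Camera gave an adjusted p = 0.000245 for glycolysis and 0.015 for matrix remodelling, each with adjusted p = 0.60 with an estimated correlation. Neither passed fry (adjusted p = 0.2 and 0.238). Metallothioneins, which bind zinc and copper, were the list that camera put higher: 3 of 8 members were called higher and 0 lower (6 higher adjusted over the list alone), MT1E by 4.88, MT1X by 3.73 and MT1G by 3.56. Their camera adjusted p was 0.0148, and adjusted p = 0.36 with an estimated correlation, and their fry adjusted p was 0.0198. In the values as deposited camera put no list higher. Ribosomal protein and hypoxia genes passed the preset camera test (adjusted p = 0.0383 and 0.0398) without a called member, with adjusted p = 0.74 for each with an estimated correlation. Their fry adjusted p values were 0.485 and 0.6. Oxidative phosphorylation had 0 of 22 called members and a median of -0.05 (camera adjusted p = 0.56), but as deposited a median of -1.29 and a camera adjusted p = 0.00461. In heat shock 1 of 11 was called higher, also adjusted over the list alone, DNAJB1 by 4.72 (camera adjusted p = 0.31). Immediate early genes had 2 of 21 lower, DUSP2 (-4.60) and EGR3 (-3.71), and 0 adjusted over the list alone (camera adjusted p = 0.29, and as deposited 0.00377 with a median of -1.17). Lipid handling had 1 of 21 lower, SOAT1 (-2.81), also adjusted over the list alone (camera adjusted p = 0.31). Cell cycle genes had MCM5 (-2.62) and PCNA (-1.60) lower and RRM2 (1.33) higher, the same adjusted over the list alone (camera adjusted p = 0.31). This list passed fry (adjusted p = 0.012), with a median of 0.69.

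Markers of other blood cells did not pass as lists. T cell, B cell and erythroid markers had 0 called members (2 erythroid ones higher adjusted over the list alone), with camera adjusted p = 0.12, 0.29 and 0.066. Among natural killer cell markers 1 of 8 was lower, also adjusted over the list alone, NKG7 by -2.55 (camera adjusted p = 0.40). Neutrophil markers had 3 of 10 lower, FCGR3B (-4.32), PROK2 (-2.88) and CMTM2 (-1.31) (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.31), with a median of 0.02 and a mean of -0.44. Platelet markers went both ways, 2 of 13 higher and 2 lower (4 and 5 adjusted over the list alone), with TREML1 at 3.58 and PF4 at -2.78 (camera adjusted p = 0.83), and a median of 0.51 beside a mean of -0.15. Dendritic cell markers did so too, with FLT3 (4.38) and TCF4 (2.65) higher and CLEC10A (-1.93) lower of 12, the same adjusted over the list alone (camera adjusted p = 0.59). Complement components had 2 of 12 higher, C5 (2.74) and CFB (2.69), and 4 lower, including CFD (-3.44), the same adjusted over the list alone, with a median of 0.24 and a mean of -0.05 (camera adjusted p = 0.79).

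Transcripts of another tissue separated the same arrays, by lists written after a first look at the values, and some measures of RNA did so too. Of 31 absorptive enterocyte genes 25 were higher and 0 lower on the macrophage arrays, with a median of 5.19. Of 15 general epithelial genes 11 were higher, among them LGALS4 (6.41) and ELF3 (6.37), with a median of 4.68. Of 19 leukocyte genes 15 were lower and 0 higher, with a median of -5.60. Their median intensity on the macrophage arrays was 30.8, 42.4 and 34.3, which is 1.01, 1.27 and 1.06 times the array median. On the monocyte arrays it was 2210, 1770 and 2740. Housekeeping genes had a median of -1.02 as normalized and -2.94 as deposited. In the values as deposited the enterocyte, epithelial and leukocyte medians were 4.15, 3.63 and -5.95. A control probe set for 28S ribosomal RNA read 10568 to 15167 on the macrophage arrays and 60.6 to 616 on the monocyte arrays. The ratio of the GAPDH 3' to the 5' control probe set was 4.65, 3.42 and 3.40 on the macrophage arrays and 3.24, 1.95 and 1.86 on the monocyte arrays. The same ratio for ACTB did not separate them, at 4.79, 3.36 and 3.93 against 3.08, 4.60 and 2.44. These differences accompany each gene group above.

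**Figure D2:**
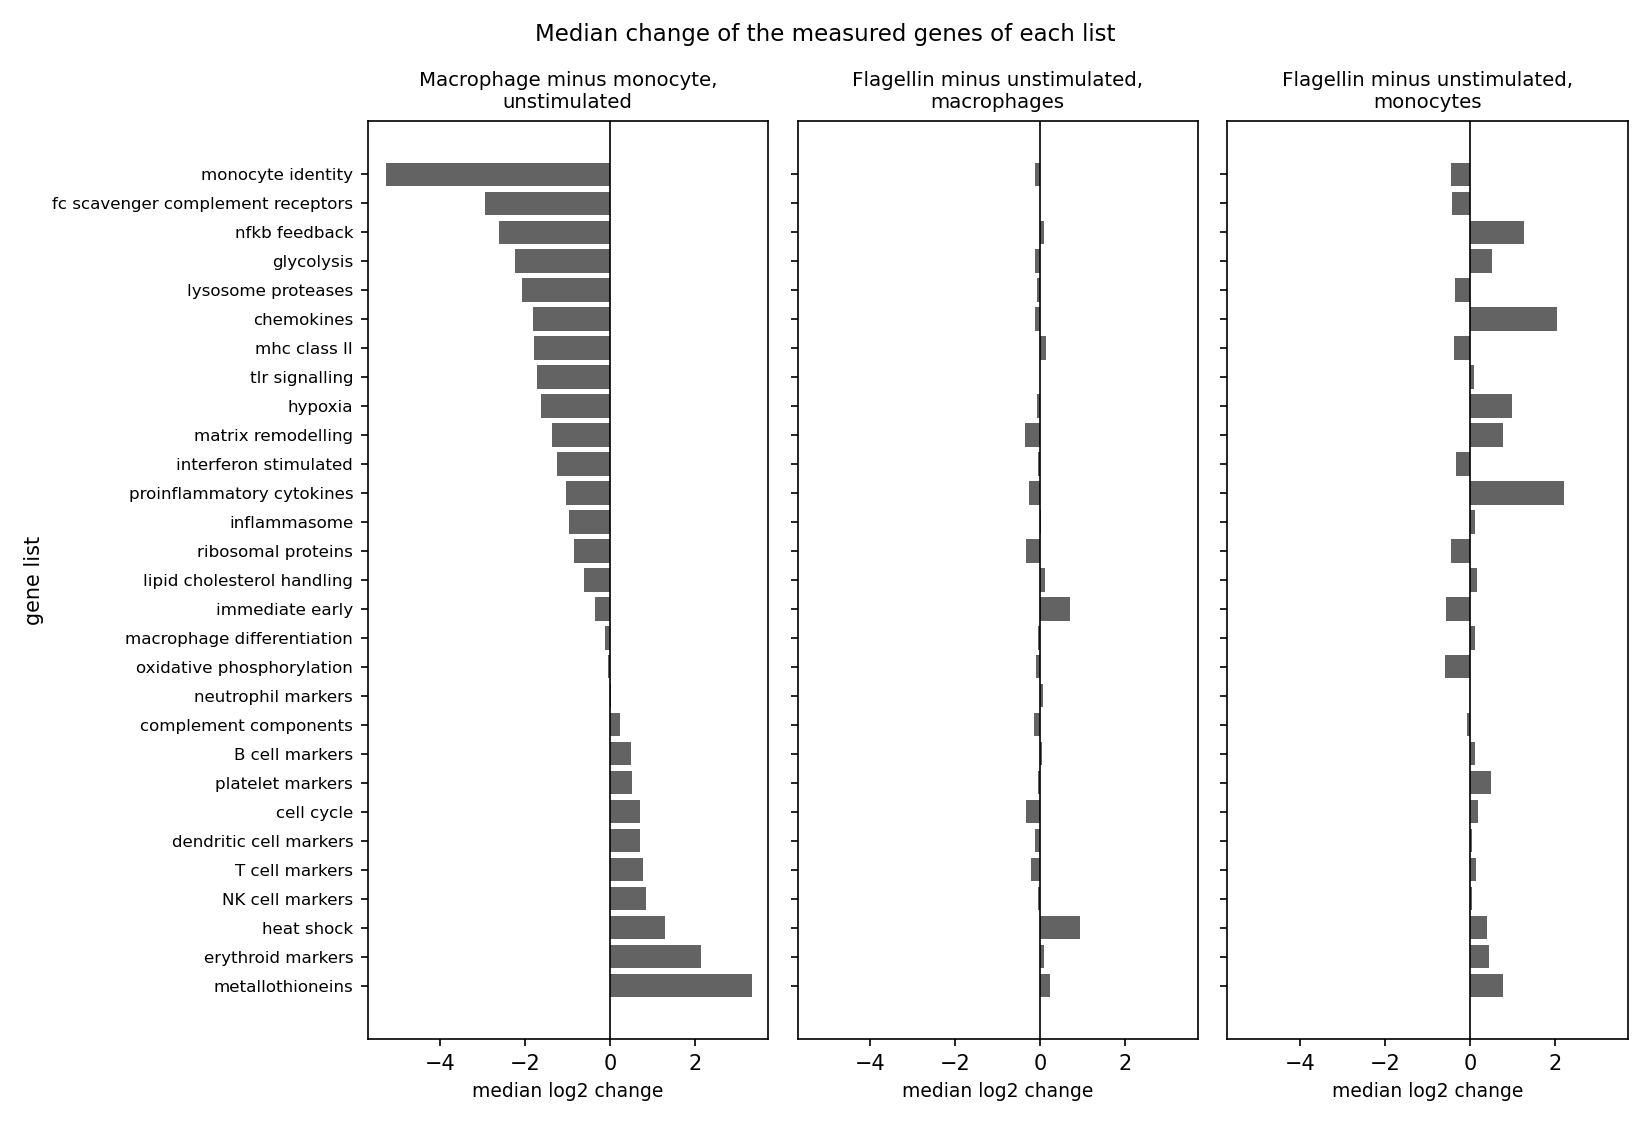
Median log2 change (x axis) of the measured genes of the 29 gene lists fixed before the data were examined (y axis), as bars, for macrophages against monocytes without flagellin and for flagellin in each cell type. The monocyte identity bar lies at -5.26 in the first panel, and the cytokine and chemokine bars at 2.22 and 2.05 in the monocyte flagellin panel.

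The second comparison asked what flagellin did in monocytes, with 1 stimulated against 2 unstimulated arrays and the stimulated array assumed to vary like the others. Among genes at an unadjusted p under 0.05, the highest values belonged to inflammatory mediators and their regulators: IL6 at 6.26 (SE 0.72), the monocyte chemoattractant CCL2 at 5.15 (SE 1.16), the immune checkpoint ligand CD274 at 4.97 (SE 0.55), the NF-kB inhibitor TNIP3 at 4.69 (SE 0.42) and TNFSF15 at 4.15 (SE 1.65). The lowest of these genes were PDK4 (-3.56), the interferon-inducible MNDA (-3.43), C16orf54 (at the floor on the flagellin array), FOS (-2.85) and MPEG1 (-2.82). Several values depended on 1 unstimulated monocyte array: with array 1 or array 2 left out, CCL2 was 3.63 or 6.68, TNFSF15 2.28 or 6.02, MNDA -1.80 or -5.06 and C16orf54 -1.47 or -4.54. No gene passed in limma: the lowest adjusted p was 0.24, for TNIP3, and 141 genes had an unadjusted p under 0.05 where 739 would be expected by chance. A count this low is not evidence of no change, because the error came from the spread of the unstimulated pairs. The 2 unstimulated monocyte arrays correlated at 0.855. The flagellin array correlated at 0.832 with array 1 and 0.959 with array 2. In the values as deposited TNIP3, CD274 and IL6 were called higher (adjusted p = 0.00687, 0.0154 and 0.0426), and after centring arrays on their medians only TNIP3 (adjusted p = 0.0346).

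As a group, 7 of 19 cytokine genes were higher with flagellin in monocytes adjusted over the list alone, and 0 over all genes, with a median of 2.22. They include IL6, INHBA (4.08) and IL1A (3.94). Camera gave an adjusted p = 1.13e-23 with the preset correlation and adjusted p = 0.43 with an estimated correlation, and fry an adjusted p = 0.072. Of 16 chemokines, 13 had values above 0 with a median of 2.05, among them CXCL5 (4.37), CXCL1 (3.82) and CCL7 (3.65), but none passed, over all genes or adjusted over the list alone. Of 21 NF-kB feedback genes, 20 were above 0 with a median of 1.27, and TNIP3 alone passed adjusted over the list alone. Camera gave adjusted p = 1.26e-08 for chemokines and 2.1e-13 for NF-kB feedback genes, and adjusted p = 0.43 for each with an estimated correlation. Fry gave an adjusted p = 0.749 for each. The CXCL5, CXCL1 and CCL7 values rest largely on unstimulated monocyte array 1, which read 3.83, 5.56 and 3.83 on the log2 scale, since array 2 read 10.2, 10.3 and 7.40 and the flagellin array 11.4, 11.8 and 9.26.

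Other lists past the preset camera test on the monocyte array shifted less, with no member of these lists passing over all genes or adjusted over the list alone. Hypoxia genes had 15 of 16 members above 0 and a median of 0.98 (VEGFA 2.56, SE 1.91), and glycolysis 15 of 19 with a median of 0.51 (SLC2A1 2.52, SE 1.56). Camera adjusted p values were 0.00095 and 0.0117, each with adjusted p = 0.77 with an estimated correlation. Matrix remodelling genes had a median of 0.78, with MMP19 at 3.02 (SE 1.76) and MMP9 at 2.99 (SE 0.70) (camera adjusted p = 0.00137, and adjusted p = 0.77 with an estimated correlation). Monocyte identity genes had 16 of 20 members below 0 and a median of -0.44, with CD14 at -2.55 (SE 0.92) (camera adjusted p = 0.00518, and adjusted p = 0.69 with an estimated correlation). All 16 ribosomal protein genes were below 0 with a median of -0.46 (camera adjusted p = 0.00265, and adjusted p = 0.77 with an estimated correlation). Oxidative phosphorylation genes had 19 of 22 members below 0 and a median of -0.59, with NDUFV1 at -1.48 (SE 1.42) (camera adjusted p = 0.0119, and adjusted p = 0.77 with an estimated correlation). Fc, scavenger and complement receptors had a median of -0.42, with CD36 at -2.46 (SE 1.60) (camera adjusted p = 0.00518, and adjusted p = 0.54 with an estimated correlation). In the values as deposited these 4 lists, monocyte identity, ribosomal protein, oxidative phosphorylation and receptor genes, did not pass, with medians of 0.16, -0.05, 0.22 and -0.30 and camera adjusted p = 0.18, 0.47, 0.83 and 0.072. Metallothioneins and platelet markers had medians of 0.77 and 0.50 (camera adjusted p = 0.0117 and 0.00712, and adjusted p = 0.56 and 0.77 with an estimated correlation). Interferon-stimulated genes had a median of -0.32 (camera adjusted p = 0.0346, and adjusted p = 0.56 with an estimated correlation). Leukocyte and housekeeping genes, in the lists written later, had medians of -0.56 and 0.10 here.

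**Figure D3:**
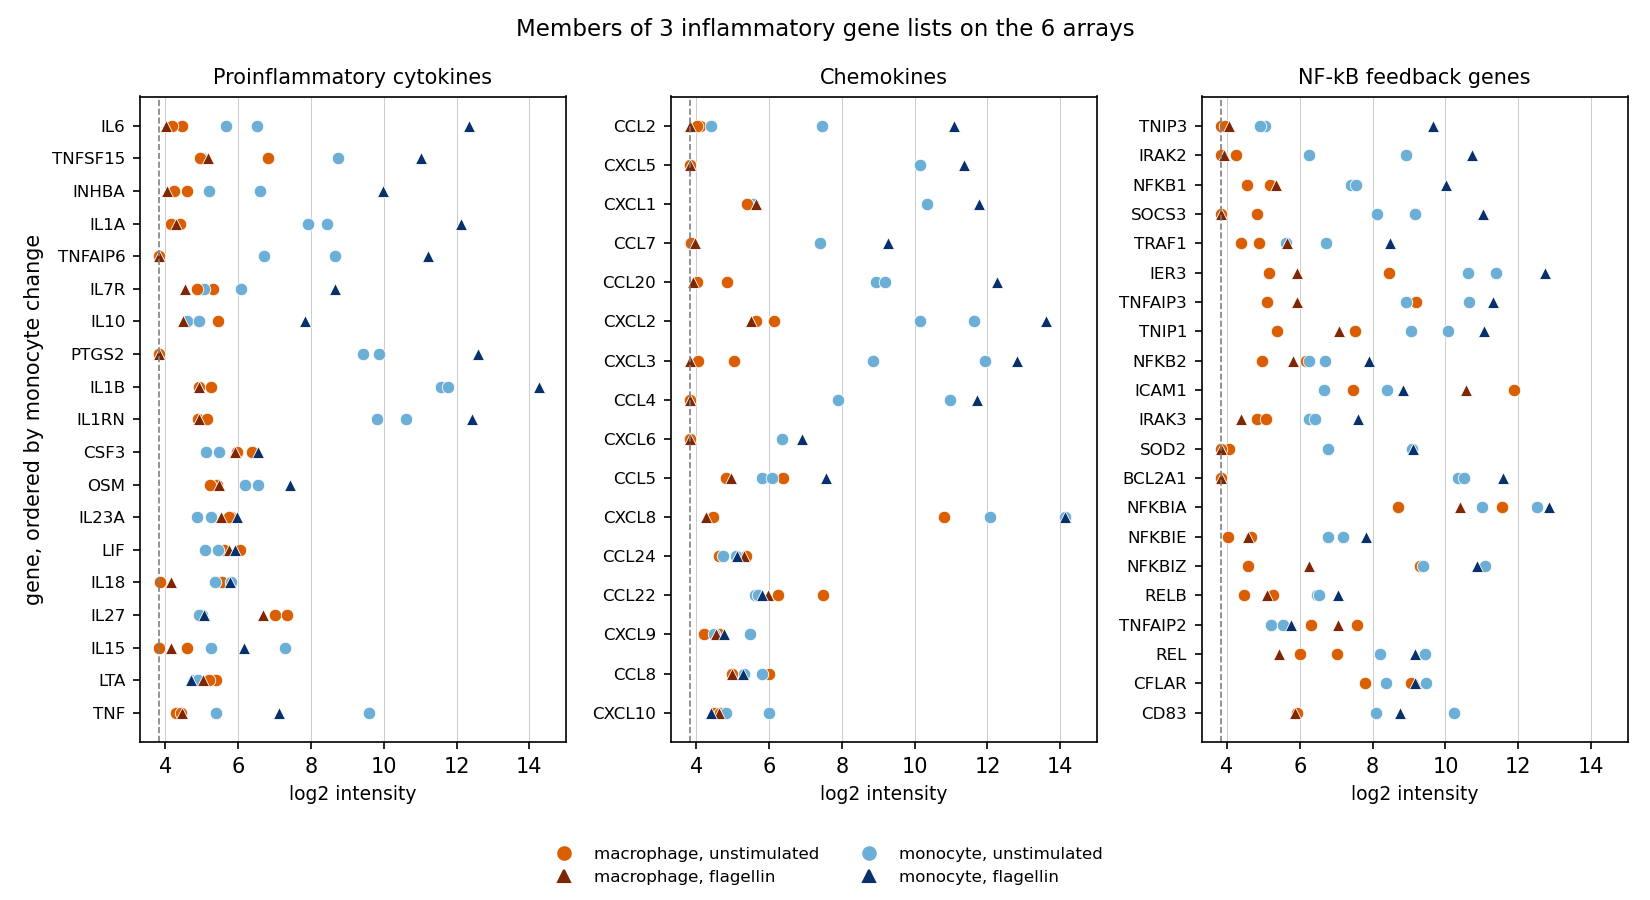
Log2 intensity after quantile normalization (x axis) of the measured cytokine, chemokine and NF-kB feedback genes (y axis, ordered by the monocyte change), with 1 point per array, circles for unstimulated and triangles for flagellin arrays and a dashed line at the floor. The monocyte flagellin triangle of IL6 lies 6.26 above the mean of the 2 unstimulated monocyte arrays.

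The third comparison asked what flagellin did in macrophages, again 1 array against 2 and with the same assumption about the lone array. Among genes at an unadjusted p under 0.05, the highest values were those of MLN, which encodes the gut hormone motilin, at 4.12 (SE 1.13), ITGA7 at 3.29, TPT1-AS1 at 3.21, LIMA1 at 3.05 and CHD9 at 3.04. The lowest of these genes were the proteoglycan SRGN at -3.69 (SE 1.07), ANKRD52 at -2.73, KSR1 at -2.41, DAO at -2.13 and FITM2 at -1.71. As deposited the first 5 were 3.27, 2.42, 2.18, 2.27 and 2.13, and the others -2.28, -1.32, -1.17, -1.35 and -1.49. With unstimulated macrophage array 1 or array 2 left out, MLN was 5.15 or 3.08, ITGA7 2.08 or 4.50, LIMA1 1.96 or 4.13 and FITM2 -0.98 or -2.43. None passed in limma (adjusted p = 1 for each), and 124 genes had an unadjusted p under 0.05. Cytokines had a median of -0.25 (camera adjusted p = 0.55), with IL10 at -0.70 (SE 0.49), and chemokines -0.11 (camera adjusted p = 0.57), with CXCL8 at -3.38 (SE 2.43). The CXCL8 value rests on unstimulated macrophage array 2, which read 10.8 on the log2 scale against 4.45 on array 1 and 4.25 with flagellin. Heat shock genes had 10 of 11 members above 0 and a median of 0.94 (camera adjusted p = 0.20), and no fixed list passed. On these arrays leukocyte genes lay at 1.01 to 1.27 times the array median, as given above.

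Taking both cell types together, the highest mean changes among genes that moved the same way in both and had an unadjusted p under 0.05 were those of TNIP3 (2.43, SE 0.30), the heat shock gene HSPA6 (2.17), MLN (2.13), KANK1 (2.12), RIN2 (2.01), the Notch ligand DLL1 (1.98), IL1A (1.98), MAP3K4 (1.94), ACSL1 (1.89) and ZNF687 (1.87). Only 8 genes met the rule in the other direction, namely SRGN (-1.86), APBB1IP (-1.45), PCNA (-1.08), SOAT1 (-1.03), KPNA5 (-0.84), DYNLT2 (-0.80), LINC02035 (-0.74) and SLC35A5 (-0.71). None passed in limma (lowest adjusted p = 1), with 94 genes at an unadjusted p under 0.05. Among cytokine genes 1 of 19 passed adjusted over the list alone, IL6 at 2.98 (adjusted p = 0.0154 over the list), and among NF-kB feedback genes TNIP3 (adjusted p = 0.00234 over the list). These mean values came from the monocyte array: IL6 was 6.26 in monocytes and -0.30 in macrophages, and TNIP3 4.69 and 0.17. Some of the genes that moved the same way hardly changed in 1 cell type. IL1A was 0.017 in macrophages. MLN read 4.88 and 5.47 on the unstimulated monocyte arrays and 5.32 on the flagellin monocyte array, on the log2 scale. By the preset correlation 10 lists passed camera, 6 of them higher, and 0 passed with an estimated correlation. In the values as deposited the ribosomal protein and oxidative phosphorylation lists did not pass (camera adjusted p = 0.455 and 0.689).

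Whether the flagellin response differed between the cell types was tested as the macrophage change minus the monocyte change. Among genes at an unadjusted p under 0.05, the lowest values were IL6 at -6.56 (SE 1.02), CCL2 at -5.38 (SE 1.64), CD274 at -5.14 (SE 0.77), TNIP3 at -4.52 (SE 0.60) and INHBA at -4.44 (SE 1.02), and the highest CITED2 at 4.01, MLN at 3.97, FOS at 3.45, DEF8 at 3.45 and BRD8 at 3.26. None passed in limma over all genes (adjusted p = 1 for each), with 125 genes at an unadjusted p under 0.05. In the cytokine list 4 of 19 passed adjusted over the list alone, IL6, IL10, INHBA and IL7R, with a list median of -2.31. Camera gave an adjusted p = 4.93e-17 with the preset correlation, adjusted p = 0.60 with an estimated correlation, and fry an adjusted p = 0.047. For chemokines and NF-kB feedback genes fry gave an adjusted p = 0.928 each. These tests rest on 1 flagellin array per cell type, and leukocyte genes were lower on all macrophage arrays, by a median of -5.60 without flagellin.

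The last comparison set the flagellin-stimulated macrophage array against the stimulated monocyte array, without replicates and so without a test. Inflammatory genes were among the largest differences: the macrophage minus monocyte value was -9.87 for the neutrophil chemokine CXCL8, -9.33 for IL1B, -8.98 for CXCL3, -8.88 for TIMP1, -8.75 for PTGS2, -8.57 for S100A8, -8.35 for CCL20, -8.32 for IL6, -8.29 for SRGN and -8.17 for AQP9. For CXCL3, PTGS2 and AQP9 the macrophage array was at the floor, so these are lower limits in size. CXCL8, S100A8, CCL20 and IL6 read 21.66, 17.05, 16.84 and 18.24 on the macrophage array as deposited, under its median of 32.4. IL1B, TIMP1 and SRGN read 35.47, 42.56 and 33.18, not far above it. The differences of these genes are therefore limits as well. In the other direction stood APOA4 (9.05), PCK1 (9.03), RBP2 (8.93), FABP1 (8.54), CYP3A5 (8.44), TMC5 (8.36), ADIRF (8.34), ZNF827 (8.26), CYP3A4 (8.15) and SI (8.12), all except APOA4 and TMC5 with the monocyte array at the floor. APOA4 and TMC5 read 14.46 and 13.95 on the monocyte array as deposited, under its median of 25.6, so all of these differences are limits too. Of 14782 genes, 1502 were at least 4-fold brighter on the macrophage and 1823 on the monocyte array. In the values as deposited these were 1058 and 2214. Of the 2032 genes called without flagellin, 2029 had the same sign here. The medians of chemokines (-5.71), monocyte identity (-4.89), NF-kB feedback (-3.74) and cytokine genes (-3.35) lay below all 10000 matched random lists. So did those of hypoxia (-3.01), glycolysis (-2.96), Fc, scavenger and complement receptor (-2.565) and Toll-like receptor genes (-2.13). Matrix remodelling and lysosome genes lay at percentiles 0.02 and 0.03, so the low lists were not only inflammatory ones. The median of the metallothioneins (2.94) lay at percentile 99.6. The macrophage differentiation median of -0.19 lay at percentile 5.94. Epithelial, leukocyte and ribosomal RNA signals separated these 2 arrays as they did the unstimulated ones.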

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

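The test of the spread between monocyte arrays and the setting of a cell type difference against the leukocyte signal were chosen after the result was seen, whereas the camera tests of that difference were planned. Also chosen after were the reading of probe sets without a single gene symbol and of the ribosomal RNA control probe set.

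A difference between the cell types in the flagellin change was found by camera with the preset correlation for 6 of the 29 lists. The median of the macrophage change minus the monocyte change was -2.31 for proinflammatory cytokines, -2.69 for chemokines, -1.28 for NF-kB feedback genes, -0.73 for matrix remodelling, -0.97 for hypoxia and -0.86 for platelet markers. With an estimated correlation adjusted p values were 0.60, 0.72, 0.72, 0.78, 0.78 and 0.78.

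Inflammatory genes thus tended to be higher with flagellin on the monocyte array, with a cytokine median of 2.22 against -0.25 on the macrophage array, though no gene passed over all genes as normalized. Spread between single monocyte arrays cannot be told apart from a response, because the lists were picked for their change on the 1 flagellin array: over their 56 genes the smaller of the 2 medians against a single unstimulated monocyte array was 1.32, beside a signed median difference of 0.32 and a median absolute difference of 0.996 between the unstimulated arrays. Too few leukocyte transcripts on the macrophage arrays to show a response stays open. A bound set beforehand would have excluded it, since for 94.1% of 17 responding genes the monocyte rise, scaled to 1.62% of leukocyte signal, exceeded the difference between the unstimulated macrophage arrays; that bound was wrong, and was set aside after the value was seen, because leukocyte genes lay at 1.01 to 1.27 times the median intensity of those arrays, so that 1.62% is only an upper limit of their share. A cell type difference in the response may exist as well: camera with an estimated correlation gave an unadjusted p = 0.0207 for the cytokine list, but it cannot be told apart from the low leukocyte signal, the leukocyte median being -5.60 without flagellin.

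Signal appeared in probe sets that stood for no gene in the comparisons above. The 28S ribosomal RNA control probe set read at least 10568 on each macrophage array and at most 616 on each monocyte array. Among probe sets without a gene symbol, 420 of 5452 passed the threshold between unstimulated macrophages and monocytes in a fit of all probe sets, 179 higher and 241 lower. Among those with several symbols 167 of 1278 passed, 58 higher and 109 lower. In that fit 4361 of all 32711 probe sets passed, a share that neither kind exceeded.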

How the results depend on the processing

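The fits to 1 cell type alone and the comparison with single monocyte arrays were chosen after seeing the data. The 2032 calls of the unstimulated comparison became 4202 in the values as deposited, 3122 with arrays centred on their medians, 1061 with the floor at the 40th percentile, 4361 over all probe sets, and 5887 in the additive model of all 6 arrays; the cause was not tested. They became 0 without the filter on dim genes and 0 to 0 with each unstimulated array left out, where 1 residual degree of freedom remained. Of the 2032 genes, 1932 were called in the same direction as deposited and 1879 after centring. The 24 named genes kept their call and direction in all settings but these 5, in which all 24 lost it and kept their direction, but with the mean of a gene's probe sets the smallest change in size was 3.14 and not 6.58. With the replicate block the count was 4048, including all 2032 in the same direction. Arrays sharing a number deviated together at a correlation of 0.25 across genes, from only 2 pairs, so this gives no pairing. Flagellin in monocytes gave 3 calls as deposited and 1 after centring; the cause was not tested. The count stayed at 0 in the other settings, including the monocyte arrays alone, and the other flagellin contrasts stayed at 0 in every setting run. Camera calls of 15, 10, 13 and 6 lists, for the unstimulated comparison, flagellin in both, in monocytes and the difference, became 0, 0, 0 and 0 with an estimated correlation. That setting was strict: 0 of 200 simulated lists without a shift had p under 0.05. Lists with an estimated correlation below 0 lost their call too. For Toll-like receptor genes (-0.0421), unadjusted camera p went from 4.04e-05 to 0.0453 in the unstimulated comparison. The loss is therefore not a measure of gene correlation alone. TLR5 in the unstimulated comparison kept -1.72 with the replicate block and passed (adjusted p = 0.0366, and 0.104 to 0.391 in the other alternatives). The macrophage flagellin value of TLR5, 0.014, changed sign to -0.001 after centring and -0.61 with the replicate block and ranged from -0.111 to 0.138 with an unstimulated array left out, and that of FITM2 to 0.147 in the macrophage arrays alone. Signal over background limits the macrophage arrays, on which the 99th percentile of intensity was 544, 276 and 508.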

Other observations

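The lists behind this part were written after a first look at the values, as were its tests except those on goblet and Paneth cell genes and on the splits of the 6 arrays. Some genes known from other cell types of the gut were also higher on the unstimulated macrophage arrays. Of 17 goblet and Paneth cell genes 5 were higher than on the monocyte arrays and 0 lower (n = 2 against 2, limma), among them the Paneth cell defensins DEFA5 (4.30, adjusted p = 0.0155) and DEFA6 (3.56, adjusted p = 0.0155) and the mucin MUC2 (2.88, adjusted p = 0.0387). Of 12 plasma cell genes 4 were higher, JCHAIN (6.92), IGKC (5.54), IGHM (3.68) and SDC1 (1.42), with a list median of 0.53. The mast cell protease CPA3 was higher (2.09, adjusted p = 0.0165), 1 of 5 in its list.

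Of 10 enteroendocrine genes 0 were called, with SST at 5.52 (SE 1.66, adjusted p = 0.070) and GIP at 4.42 (SE 1.44, adjusted p = 0.081). This list had a median of 1.30 for flagellin in macrophages, led by MLN, with camera adjusted p = 0.00113, and adjusted p = 0.72 with an estimated correlation. Goblet and Paneth cell genes went the other way there, with 14 of 17 below 0, a median of -0.34 and camera adjusted p = 0.0113, and adjusted p = 0.72 with an estimated correlation. Neither list passed fry (adjusted p = 0.962 for each), and no member passed over all genes or adjusted over the list alone. This contrast rests on 1 flagellin array. Of 14 hepatocyte genes 1 was higher, CPS1 (2.91), which the intestine also expresses, with a list median of 0.52. Of 12 stromal genes 1 was higher, CALD1 (1.91), and of 9 endothelial genes 1 lower, ENG (-2.92).

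The macrophage arrays were thus bright for epithelial and dim for myeloid transcripts. Less labelled RNA of every kind is argued against for the bright part, and as the sole cause for the dim part. Enterocyte genes were higher by a median of 4.15 in the values as deposited. The monocyte identity list, fixed beforehand, lay below housekeeping genes by -2.55 as deposited (two-sided permutation test of genes between the lists, p = 1e-04). As normalized its difference was -4.24. That p-value takes genes as units, not arrays. Housekeeping genes were themselves lower by a median of -2.94 as deposited, so less RNA as a part of the dimness is not excluded. The leukocyte list, written after its genes were seen to be dim, differed from housekeeping genes by -3.01 as deposited and -4.59 as normalized. Quantile normalization is argued against for the dim part, since the monocyte identity median was -5.49 as deposited. The leukocyte and enterocyte medians were -5.95 and 4.15 as deposited, in lists written after a first look at the values. RNA from intestinal epithelial cells in these samples is a candidate explanation. Goblet and Paneth cell genes, not looked at when the pattern was found, had a median of 1.94 as deposited against 0.93 for hepatocyte genes. Other lists outside the epithelium were also above 0 as deposited, with medians of 1.23 for stromal, 0.99 for mast cell, 0.83 for plasma cell and 0.405 for endothelial genes. Deposited APOA1 intensity was 5081 to 9277 against 24.1 and 40.4 in unstimulated monocytes. Expression of the epithelial genes by the macrophages themselves cannot be told apart from RNA of epithelial cells in bulk RNA, and the labels name no tissue or sort. The macrophage differentiation median was -0.13. Leukocyte genes lay at 1.01 to 1.27 times the array median, so macrophages expressing epithelial genes would have lacked a clear leukocyte signal.

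A fit of all 6 arrays with additive terms called 5887 genes between the 3 macrophage and 3 monocyte arrays. As many were called in 1 of the 10 splits of the arrays into 3 and 3, the real one, and the highest count of the other splits was 0. With 10 splits the share cannot fall under 0.05.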
